A study of Oryza sativa with 6 samples.

How the data were processed

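RNA from young leaves of 11-day-old Minghui63 rice was hybridised to the Affymetrix rice genome array, 1 sample per array, with 3 control and 3 RNAi samples. Groups and replicate numbers were taken from the sample titles. The deposited values are 1 probe set intensity per array on a linear scale, made with GCOS 1.2, per the submitters' processing notes. How the probes were summarised or scaled is not given in the sources used here, and no detection calls were used. The trimmed mean (2% off each end) of the deposited intensity was 500.1 in control replicate 3 and 99.86 to 117.8 in the other 5 arrays, so the deposited arrays differed in scale. The deposited fluidics and scanner records hold other settings and no expression values. Their headers give 1 hybridization date and time for all control arrays and a later one for all RNAi arrays. Arrays that share this entry are called a wash run here. All control arrays were also scanned before all RNAi arrays, and the fluidics module had the same number as the replicate.

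Each array was multiplied to a common 2%-trimmed mean of 500, 16 was added and log2 taken. Fold changes are on this scale, which understates changes of low genes. Of 57381 probe sets, 123 control and 64 reporter probe sets entered the scaling but not the test. The lower 50% of the remaining 57194 by mean log2 signal over the 6 arrays were left out, which left 28597. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment over the tested probe sets). The submitters' text names SAM, which was written here with a fudge factor and all 20 label permutations and run as an alternative. The p-values measure the spread between these samples.

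Probe sets were named through the array's platform annotation and a RefSeq gene table of the assembly ASM3414082v1, from a japonica rice, whose coordinates were used only for which genes neighbour each other. In it 22436 probe sets had 1 gene, 95 had several and 34850 had none listed. All 22436 were found in the gene table, and 2457 of 17905 genes had a name other than a locus number or clone name. A probe set with no gene listed is unnamed here. These tables hold no gene descriptions, so the lists of gene groups, fixed before the data were examined, were matched by symbols and synonyms. The symbol patterns were written after the annotation was seen and before any comparison of expression was run. A gene with a described product was read as a gene with such a name.

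There were 35 lists: sirtuins and histone deacetylases, histones, chromatin modifiers, transposable elements, pathogenesis-related proteins, NBS-LRR proteins, WRKY and NAC factors, diterpenoid phytoalexins, phenylpropanoids and lignin, peroxidases, antioxidant enzymes, glutathione S-transferases, oxidative burst, programmed cell death, chlorophyll breakdown, nucleases and DNA repair, photosynthesis, jasmonate, salicylate, ethylene, abscisic acid, heat shock, endoplasmic reticulum folding, calcium, receptor-like kinases, cytochrome P450, cell wall, auxin, ribosome, proteasome, and markers of root, dividing cells, seed and pollen. Each gene entered with its probe set of highest mean signal. Lists of at least 5 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with the estimated correlation and fry as alternatives. Fry asks whether a list's genes move, on balance, one way and does not compare them with other genes.

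Genes to name were fixed by a rule before the data were examined. They were OsSRT1 and OsSRT2, which have no named probe set and were not analysed here, the 12 largest rises and 12 largest falls among named genes past the threshold with groups that did not overlap, and from each list up to 4 members with the smallest adjusted p, from which the text gives examples. CM-LOX2, the AOS genes, OPR4, OPR-1, OPR7, RAB16D, rab25, Dhn1 and the small heat shock and calmodulin-like genes that did not pass were added after their values were seen. The medians of lists were also set against 10000 random lists of the same size and signal. Alternatives fixed in advance were the scaling, the pseudocount (1 and 64), the filter, the replicate number as a block, leaving out each array, eBayes without a trend, SAM, Welch's test, leaving out probe sets that read several genes, and 1 probe set per gene. A block for wash run could not be fitted, since each run held 1 group, and a block for fluidics module is the replicate block.

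The tests were checked on simulated arrays drawn from the means and spreads of the 28597 probe sets, with 200 changed probe sets in each of 5 runs. Limma found 28.4% of changes of 2-fold and 69.8% of 4-fold, with 3.7% false calls on average. SAM found 21.6% and 62.6%, and Welch's test with adjustment 2.2% and 5%. The simulated noise was independent between probe sets, with no shared array effect or wash run, so these rates need not hold for the real arrays.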

Results

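Transcript levels were measured with the Affymetrix rice genome array, on which a set of short probes reports each transcript, in young leaves of the indica rice variety Minghui63. There were 3 control arrays from untransformed plants and 3 arrays from plants carrying a construct for RNA interference against OsSRT1, a rice member of the sirtuin family of NAD-dependent deacetylases. The construct was a hairpin of 412 bp from the 3' untranslated region of OsSRT1, a stretch chosen because it differs from OsSRT2. Leaves were taken at 11 days, when the RNAi plants did not yet show the lesions that they develop later, so the comparison addressed which transcripts differed before visible cell death. The submitters describe the arrays as biological repeats. The titles call the RNAi samples transgenic line LM1, transgenic line LM2 and transgenic line LM3, which reads as 3 lines. They do not say outright whether the number marks a line or a sample of 1 line, and it is used here as the replicate number. On the scaled values the median signal of an array lay between 40.16 and 46.13, and 5.7 was the lowest mean log2 value of a tested probe set, a signal of 36.1. The number of arrays limits the precision of every value given here.

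The hairpin's target comes first in a knockdown design. No probe set was named OsSRT1 or OsSRT2 in the annotation used, so their levels were not analysed here and the labels of the RNAi arrays were not checked by their target. The arrays did separate by label, which is also the split by wash run, so this separation does not check the labels. Correlations of log2 signal over the tested probe sets ran from 0.9671 to 0.9789 within the groups and from 0.954 to 0.9639 between them, and no 2 arrays were copies of each other.

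Between RNAi and control leaves, a JAZ repressor of jasmonate signalling and an ethylene-forming enzyme went from near the floor to high signal, the dehydrin genes RAB16B, RAB16C and RAB21 rose, and the small heat shock protein genes HSP17.4 and HSP18.1, the oxophytodienoate reductase genes opda and OPR10 and a serotonin-forming cytochrome P450 fell. JAZ2 (also named OsTIFY5) had a scaled signal of 3.98 ± 1.04 (SD, n = 3) in the controls and 1390 ± 209 in the RNAi arrays, a log2 fold change of 6.12 ± 0.21 (SE; adjusted p = 6.43e-06). The only tested probe set of JAZ2 has a name that marks it as reading several genes, so this rise cannot be assigned to JAZ2 alone. CYP71P1, which converts tryptamine to serotonin and is the product of the Sekiguchi lesion locus SL, had 590 ± 101 in the controls and 28.9 ± 17 in the RNAi arrays, a log2 fold change of -3.81 ± 0.3 (adjusted p = 0.000335). Of 28597 probe sets tested with limma, 601 (2.1%) passed an adjusted p of 0.05, 312 of them higher and 289 lower in the RNAi arrays. Of the 601, 434 differed by a log2 fold change of 1 or more, 248 upward and 186 downward. Changes of at least 4 on the log2 scale were found at 26 probe sets, 25 of them higher in the RNAi arrays. At all 601 the 3 RNAi values lay outside the range of the 3 control values, as they did at 22.4% of all tested probe sets, where chance gives 10%. By annotated gene, 350 of 14993 tested genes passed, 149 higher and 201 lower.

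The count of calls depended on single arrays. It was 355 without control replicate 1, 233 without control replicate 2, 334 without control replicate 3, 902 without RNAi replicate 1, 358 without RNAi replicate 2 and 369 without RNAi replicate 3. The share of higher calls, 51.9% with all arrays, was 61.7% without control replicate 1, 70.8% without control replicate 2, 61.4% without the trend in eBayes and 42.7% with 1 probe set per annotated gene. The count also depended on the scale of the signals. As deposited, control replicate 3 was on a scale about 5 times that of the other arrays, and without rescaling the median log2 fold change of all probe sets was -0.52 and 37 probe sets passed, 64.9% of them higher in the RNAi arrays against 51.9% after scaling. All control arrays were washed in 1 run and all RNAi arrays in a later one, so wash run and group cannot be told apart. A separate test of each probe set, with no shared estimate of its spread, called 0 after adjustment, with 3001 at an unadjusted p under 0.05, where limma had 4471 and 1430 would fall by chance. The series' design text states 521 genes up and 213 down with SAM at a q of 5%. SAM run here on the 28597 probe sets that passed the signal filter of this report called 551, 349 up and 202 down. With no filter on low signal, a setting chosen after seeing the data, it called 105, 103 of them up. These are counts of probe sets, and the submitters' filter and normalization before SAM are not given in the sources used here, so the counts are not like for like.

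Among genes with a name, the largest rises after JAZ2 were those of ACO1, OsPht1;11, RAB16B, RAB16C, OsPM19L1, IAA31, PORA, LEA19, RAB21, STAR2 and CESA4. ACO1, a 1-aminocyclopropane-1-carboxylate oxidase that makes ethylene, had a signal of 19.2 ± 27.4 in the controls and 929 ± 115 in the RNAi arrays (log2 fold change 5.01 ± 0.45, adjusted p = 0.000682). Where 1 group lay near the floor, the size of a change was set in part by the 16 added to each signal: with 1 or 64 added instead the log2 fold change was 8.13 or 4.4 for JAZ2, 6.6 or 3.62 for ACO1, 3.53 or 1.98 for OsPht1;11 and -4.44 or -2.82 for CYP71P1. The phosphate transporter gene OsPht1;11, best known from mycorrhizal roots, rose from 23.9 ± 5.66 to 286 ± 57.1 (log2 fold change 2.91 ± 0.27, adjusted p = 0.000727), while a second probe set of that gene had a log2 fold change of 1.68 that did not pass. OsPM19L1 rose by 2.07 on the log2 scale, IAA31 by 1.91, PORA, a protochlorophyllide oxidoreductase of chlorophyll synthesis, by 1.7, and STAR2, a subunit of a transporter for aluminium tolerance, by 1.59. The largest falls after CYP71P1 were those of HSP17.4, COPT2, ABCG48, HSP18.1, OPR10, HSF10, ALN, opda, AT5, BC1L9 and OsSPX2. The copper transporter gene COPT2 fell from 435 ± 84.8 to 76.3 ± 21.8 (log2 fold change -2.3 ± 0.25, adjusted p = 0.00208). The log2 fold change was -2.13 for the transporter gene ABCG48, -1.76 for the allantoinase gene ALN, -1.71 for the acyltransferase gene AT5, -1.66 for the COBRA-like gene BC1L9 and -1.41 for OsSPX2, of a family tied to phosphate sensing.

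**Figure D1:**
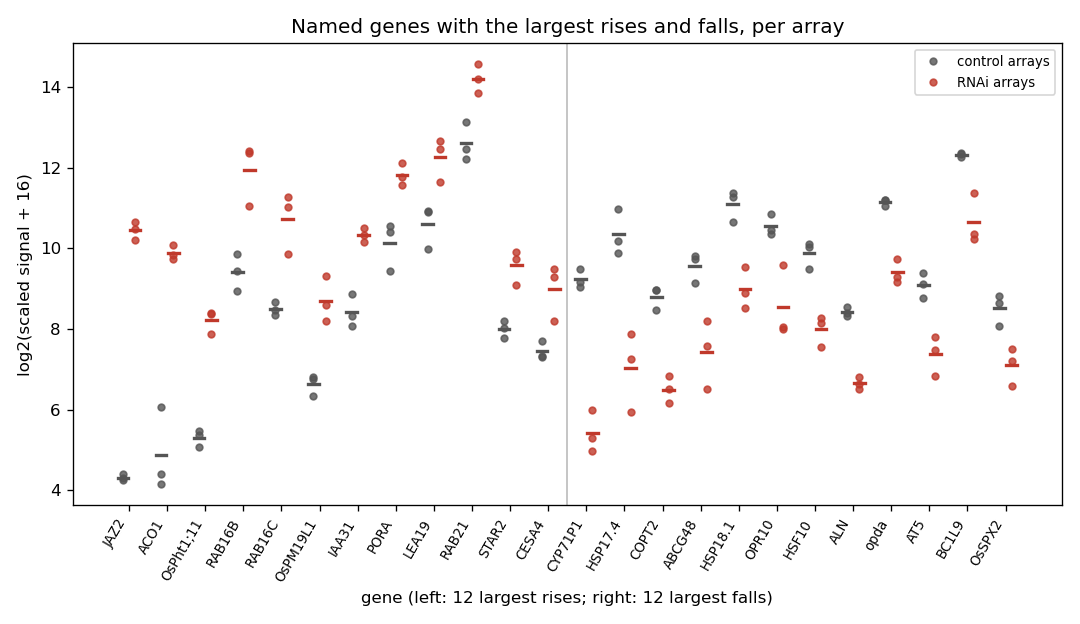
Log2 of the scaled signal plus 16 on each of 3 control (grey) and 3 RNAi (red) arrays for the 12 named genes with the largest rises (left) and the 12 with the largest falls (right). Points are arrays and bars are group means. In each gene the RNAi arrays lie outside the range of the control arrays, and JAZ2 spans a log2 fold change of 6.12.

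Of these 24 genes, 14 passed in each of the 6 fits that left out 1 array. RAB21 had an adjusted p of 0.0557 without control replicate 1 and PORA 0.0671 without RNAi replicate 3. STAR2 had 0.0634 without control replicate 2 and 0.0502 without RNAi replicate 2, and AT5 reached up to 0.0938 without control replicate 2, control replicate 3 or RNAi replicate 2. ABCG48 and BC1L9 were lost without any 1 of the control arrays or RNAi replicate 2. LEA19 and OPR10 were lost in 5 of 6 such fits, passing only without RNAi replicate 2, CESA4 in 5, passing only without RNAi replicate 1, and OsSPX2 in all 6.

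Most tested genes of the jasmonate list had lower mean levels, few of them past the threshold, while JAZ2 rose. As a group the list passed with camera's preset correlation and not with an estimated one. Of 34 tested members 1 rose, 3 fell and 30 did not pass; adjusted over the list alone, 2 rose and 13 fell. The list's median log2 fold change was -0.23, with 26 members lower and 8 higher (camera adjusted p = 4.72e-05, and adjusted p = 0.189 with an estimated correlation). The oxophytodienoate reductase genes opda (also named OsOPR1) and OPR10 (also named OsOPR4) fell, opda from 2260 ± 134 to 672 ± 151 (log2 fold change -1.75 ± 0.17, adjusted p = 0.000986) and OPR10 from 1500 ± 293 to 415 ± 298 (log2 fold change -2.01 ± 0.39, adjusted p = 0.037). JAZ11, for which the annotation also lists OsJAZ2 as a synonym, fell by 0.64 ± 0.09 on the log2 scale (adjusted p = 0.00982, 0.0767 without control replicate 2 and 0.0892 without the trend in eBayes). The lipoxygenase gene CM-LOX2 had a log2 fold change of -1.82 and an adjusted p of 0.0621, and the allene oxide synthase genes went both ways without passing, with -0.66 and -0.95 for 2 genes named AOS (adjusted p = 0.0997 and 0.265) and 0.92 for AOS3 (0.435). The other 3 oxophytodienoate reductase genes did not pass, with -0.98 for OPR4, -0.94 for OPR-1 and -0.14 for OPR7. These genes are in the list by name, and which of the 5 reductases takes part in jasmonate synthesis was not examined. In the ethylene list ACO1 rose, none fell and 10 of 11 did not pass, and 2 rose adjusted over the list alone. The ethylene receptor gene ETR2 had a log2 fold change of 0.56 ± 0.14 (adjusted p = 0.101).

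The dehydrin genes RAB16B, RAB16C and RAB21 rose, and the wider list of abscisic acid and dehydration genes did not pass as a group. Of 77 tested members 4 rose, 1 fell and 72 did not pass, and adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.853). The genes that rose were RAB16B, RAB16C and RAB21, which encode dehydrins, and LEA19 (also named OsLEA3-1), a late embryogenesis abundant protein. RAB16B went from 691 ± 222 to 4270 ± 1890 (log2 fold change 2.53 ± 0.37, adjusted p = 0.00988) and RAB21 from 6450 ± 2230 to 19300 ± 4790 (log2 fold change 1.6 ± 0.24, adjusted p = 0.0121). RAB16C rose by 2.23 and LEA19, on a probe set whose name marks it as reading several genes, by 1.66 on the log2 scale. Without the trend in eBayes none of these 4 passed (adjusted p = 0.0589 for RAB16B, 0.0552 for RAB16C, 0.0742 for RAB21 and 0.117 for LEA19). The other 3 dehydrin genes did not pass, with log2 fold changes of 1.5 for RAB16D, -0.09 for rab25 and -0.46 for Dhn1. OsSAPK2, a kinase of abscisic acid signalling, fell by 0.49 ± 0.09 (adjusted p = 0.029, past the threshold in 1 of the 6 fits that left out an array).

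The small heat shock protein genes HSP17.4 and HSP18.1 fell. Among heat shock proteins, chaperones and heat shock factors, 1 of 46 tested members rose, 3 fell and 42 did not pass, and 2 rose and 6 fell adjusted over the list alone. The median was -0.12, with 37 members lower (camera adjusted p = 0.00214, adjusted p = 0.695 with an estimated correlation). Without RNAi replicate 1 the median was -0.07 and the adjusted p 0.0503. HSP17.4 fell from 1350 ± 559 to 134 ± 87.2 (log2 fold change -3.32 ± 0.47, adjusted p = 0.00844) and HSP18.1 from 2220 ± 551 to 512 ± 192 (log2 fold change -2.11 ± 0.28, adjusted p = 0.00573). The other 15 small heat shock protein genes did not pass, with 12 lower, 3 higher and log2 fold changes from -1.26 (hsp17.9) to 0.79 (HSP26.7) around a median of -0.28. HSF10, a heat shock factor also named HSFA4D and known as the product of the spotted leaf gene SPL7, fell from 938 ± 211 to 244 ± 64 (log2 fold change -1.88 ± 0.25, adjusted p = 0.00573). The member that rose is annotated as ARD1, an acireductone dioxygenase of methionine salvage, with a heat shock factor, HSFA2C, among its synonyms (log2 fold change 1.23 ± 0.15, adjusted p = 0.00369), and a second probe set of that gene had -0.17. In the list of protein folding in the endoplasmic reticulum 0 of 19 passed, also adjusted over the list alone, and BIP1 had a log2 fold change of -0.78 ± 0.38 (adjusted p = 0.369), which was -0.24 without RNAi replicate 1.

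The calmodulin-like calcium sensor genes CML15, CML5 and CML27 fell. In the calcium signalling list 1 of 46 tested members rose, 3 fell and 42 did not pass, and adjusted over the list alone 1 rose and 4 fell. The median was -0.15 (camera adjusted p = 0.00193, adjusted p = 0.189 with an estimated correlation, and 0.108 on the signals as deposited). CML15 had a log2 fold change of -1.24 ± 0.17, CML5 one of -1.3 ± 0.22 and CML27 one of -0.96 ± 0.13 (adjusted p = 0.0078, 0.0208 and 0.0078). CML15 and CML27 reached 0.057 and 0.052 without control replicate 2, and CML5 passed in 2 of the 6 fits that left out an array. The other 17 genes of this family did not pass, with 10 lower, 7 higher and log2 fold changes from -0.87 (CML31) to 0.43 (CML20) around a median of -0.17. CBL9, a calcineurin B-like sensor, rose by 1.08 ± 0.22 (adjusted p = 0.0486), a call lost in all 6 fits that left out an array. The names of the CML5 and CBL9 probe sets mark them as reading several genes.

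Genes for diterpenoid phytoalexins, the terpene antimicrobials of rice, were lower as a group with camera's preset correlation and not with an estimated one. Singly, 0 of 14 tested members passed, and 3 fell adjusted over the list alone. The median was -0.68, with 12 members lower (camera adjusted p = 0.00137, adjusted p = 0.695 with an estimated correlation). Without RNAi replicate 1 the median was -0.26 and the adjusted p 0.0567. CYP71Z7 had signals of 2280 ± 411 and 860 ± 534 (log2 fold change -1.66 ± 0.51, adjusted p = 0.157), OsMAS a log2 fold change of -1.15 ± 0.35 (adjusted p = 0.154) and CYP71Z6 one of -0.8 ± 0.18 (adjusted p = 0.064). Without RNAi replicate 1 the values were -0.94 for CYP71Z7, which then passed (adjusted p = 0.0238), and -0.73 for OsMAS. With quantile normalization CYP71Z6 passed (-0.85, adjusted p = 0.0337). The cytochrome P450 list shares members with it. There CYP71P1 fell, none rose and 23 of 24 did not pass, 2 rose and 6 fell adjusted over the list alone, and the median was -0.4 (camera adjusted p = 0.0104, adjusted p = 0.695 with an estimated correlation). That median was -0.12 and the adjusted p 0.0759 without RNAi replicate 1, and -0.31 and 0.0734 without control replicate 3. CYP88A5, an ent-kaurenoic acid oxidase of gibberellin synthesis, had a log2 fold change of 1.08 ± 0.23 (adjusted p = 0.0523) and passed with the replicate number as a block (0.0164) and with 64 added to the signals (0.0462). CYP701A19 had 0.83 ± 0.19 (adjusted p = 0.0675) and passed with SAM.

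Other defence genes that could be matched by name showed few calls. Only 2457 of 17905 genes had a name, so these lists leave out unnamed members and do not describe whole families. Among pathogenesis-related proteins 1 of 11 fell, 0 rose and 10 did not pass, and 2 fell adjusted over the list alone. The chitinase gene Cht6 fell from 1580 ± 276 to 690 ± 134 (log2 fold change -1.18 ± 0.19, adjusted p = 0.0154, and up to 0.098 without control replicate 2, control replicate 3 or RNAi replicate 2). PBZ1, a PR10 protein induced by probenazole, had 20900 ± 2060 in the controls and 8010 ± 4260 in the RNAi arrays (log2 fold change -1.57 ± 0.39, adjusted p = 0.0914), and -1 with an adjusted p of 0.0036 without RNAi replicate 1. Of 22 salicylate and immune regulators 1 fell and 0 rose, also adjusted over the list alone. That gene was NH3, an NPR1 homologue, with a log2 fold change of -0.61 ± 0.1 (adjusted p = 0.019, past the threshold in 1 of the 6 fits that left out an array), and the chitin receptor gene CEBIP had 1.28 ± 0.47 (adjusted p = 0.236), which was 0.61 without RNAi replicate 1. None of 6 WRKY factors passed over all genes, and 1 rose adjusted over the list alone, WRKY9 with a log2 fold change of 0.89 ± 0.24 (adjusted p = 0.111 over all genes, and 0.0342 without RNAi replicate 3). OsWRKY76 had -0.99 ± 0.37 (adjusted p = 0.242) and passed without RNAi replicate 1 (-1.46, adjusted p = 0.0124), and OsWRKY62 had -0.67 ± 0.3 (adjusted p = 0.333), and -1.04 without control replicate 3 (adjusted p = 0.0804). None of 6 NAC factors, 25 phenylpropanoid and lignin genes or 7 receptor-like kinases passed in either count. PAL06, a phenylalanine ammonia-lyase, had a log2 fold change of -1.24 ± 0.39 (adjusted p = 0.164), and -0.8 without RNAi replicate 1. The 4-coumarate-CoA ligase gene 4CL5 had -0.83 ± 0.22 (adjusted p = 0.105, and 0.0414 without RNAi replicate 2). The list of NBS-LRR resistance proteins had 0 tested members.

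Cell wall genes were higher as a group with camera's preset correlation and not with an estimated one. Of 40 tested members 2 rose, 0 fell and 38 did not pass, and 9 rose and 1 fell adjusted over the list alone. The median was 0.35, with 32 members higher (camera adjusted p = 0.000269, adjusted p = 0.695 with an estimated correlation). On the signals as deposited the median was -0.25 where that of all probe sets was -0.52. The expansin gene EXPB6 rose from 215 ± 53.7 to 501 ± 27.6 (log2 fold change 1.19 ± 0.21, adjusted p = 0.0243, past the threshold in 2 of the 6 fits that left out an array). CESA4, a cellulose synthase of secondary walls, rose from 160 ± 28.5 to 529 ± 220 (log2 fold change 1.54 ± 0.32, adjusted p = 0.0491), and a second probe set of that gene had 0.71. CESA3 had a log2 fold change of 0.87 ± 0.21 (adjusted p = 0.0855) and its second probe set passed with 1.33. Without RNAi replicate 1 CESA3 passed (1.05, adjusted p = 0.0278), as did the expansin gene EXPB7, which had 1.09 ± 0.25 (adjusted p = 0.0688) with all arrays. In the auxin list 2 of 47 rose, 1 fell and 44 did not pass, with 3 and 3 adjusted over the list alone. The Aux/IAA repressor gene IAA31 rose from 336 ± 102 to 1280 ± 154 (log2 fold change 1.91 ± 0.22, adjusted p = 0.00247). IAA21 rose by 0.64 ± 0.12 and IAA2 fell by 0.65 ± 0.11 (adjusted p = 0.0295 and 0.0181, each past the threshold in 1 of the 6 fits that left out an array).

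The fixed lists of chromatin, cell death and oxidative stress genes held no calls over all genes with all 6 arrays and the trimmed-mean scaling. This covers only the genes matched by name to these lists. CYP71P1 and HSF10, given above as products of lesion and spotted leaf loci, passed and were counted in other lists. None of 34 chromatin modifiers passed in either count, and JMJ706, a histone demethylase, had a log2 fold change of -0.53 ± 0.14 (adjusted p = 0.101), and passed without RNAi replicate 1 (-0.63, adjusted p = 0.04). None of 6 histone genes passed in either count, with H2B.11 at -0.51 ± 0.15 (adjusted p = 0.146), nor did HDA703, the single tested member of the list of sirtuins and histone deacetylases, at 0.5 ± 0.4 (adjusted p = 0.596), which was 0.11 without RNAi replicate 1 and 0.89 without RNAi replicate 3. The list of transposable element genes matched 0 probe sets. Of 15 genes of programmed cell death and proteases none passed over all genes and 1 fell adjusted over the list alone. This was BI-1, an inhibitor of cell death, with 10800 ± 1720 in the controls and 7490 ± 326 in the RNAi arrays (log2 fold change -0.52 ± 0.13, adjusted p = 0.0851 over all genes), which passed without control replicate 3 (-0.65, adjusted p = 0.0321). None of 22 genes of nucleases and DNA repair, 4 of chlorophyll breakdown and senescence, 28 antioxidant enzymes, 3 peroxidases or 6 glutathione S-transferases passed in either count. The superoxide dismutase gene sodCp had a log2 fold change of 1.01 ± 0.3 (adjusted p = 0.144) and SODCC.2, another, 0.62 ± 0.19 (adjusted p = 0.158). Without RNAi replicate 1 both passed, with 1.42 (adjusted p = 0.00149) and 0.79 (adjusted p = 0.0386), and the nuclease gene BBD1, at 0.68 with all arrays, passed without control replicate 3 (1.03, adjusted p = 0.0486) and had 0.41 without control replicate 1 (adjusted p = 0.503). With quantile normalization the metallothionein gene MT2B passed with 0.53 (adjusted p = 0.0428), against 0.43 ± 0.1 (adjusted p = 0.0814) with the scaling used elsewhere. In the oxidative burst list 0 of 9 passed over all genes and 1 rose adjusted over the list alone, the germin-like gene GER1 with 0.72 ± 0.19 (adjusted p = 0.113 over all genes). Of its 9 members 6 were lower, and its median of -0.39 lay below the middle 95% of random lists of the same size and signal, -0.22 to 0.25, while camera did not pass (adjusted p = 0.484).

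The photosynthesis list passed camera toward lower levels but was not set apart from other genes of the same signal, with 11 of 14 members lower, a median of -0.15 and none past the test singly, also adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.695 with an estimated correlation). The median lay within the middle 95% of 10000 random lists of the same size and signal, -0.21 to 0.02. The shift did not pass with quantile normalization, with no filter on low signal, on the signals as deposited (adjusted p = 0.591), or without control replicate 1, RNAi replicate 1 (0.193) or RNAi replicate 2. The light-harvesting gene LHCP had 37600 ± 2230 and 31800 ± 5410 (log2 fold change -0.25 ± 0.12, adjusted p = 0.372), and -0.11 without RNAi replicate 1. None of 24 ribosomal protein genes or 19 proteasome and ubiquitin genes passed in either count, with RPL5 at 0.36 ± 0.1 (adjusted p = 0.117) and OsRPT1b at 0.47 ± 0.17 (adjusted p = 0.232).

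**Figure D2:**
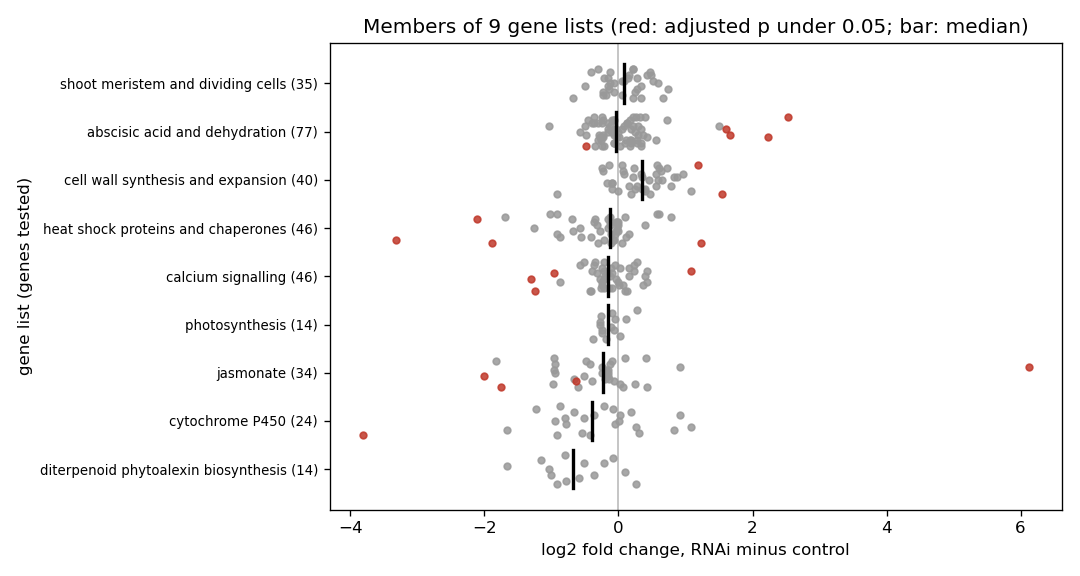
Log2 fold change (RNAi minus control) of each tested member of the 7 gene lists past a camera adjusted p of 0.05 and of 2 further lists. Each point is 1 gene, red where its adjusted p was under 0.05, and the black bar is the list's median. Medians run from -0.68 for diterpenoid phytoalexins to 0.35 for the cell wall.

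Of 35 lists 27 had enough tested members for camera, and 7 passed, 6 lower and 1 higher. The medians of 6 of these 7, all but photosynthesis, lay outside the middle 95% of random lists of the same size and signal, as did that of the oxidative burst among the lists that did not pass. The 7 lists were picked on these same fold changes, and random lists ignore correlation between members, so this adds no separate support. With an estimated correlation 0 of 27 passed, and at an unadjusted p under 0.05 the jasmonate list had 0.014 and calcium signalling 0.012. Median, mean and test differed in sign for the lists of abscisic acid and dehydration, auxin, salicylate, cell death and antioxidants, none of which passed, and median and mean also for the small lists of peroxidases and chlorophyll breakdown.

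No marker of another tissue passed over all genes. In the list of shoot meristem and dividing cells 0 of 35 passed in either count and the median was 0.09 (camera adjusted p = 0.484). There were 3 root, 3 seed storage and 2 pollen markers among the tested genes, of which 1 root marker fell adjusted over the list alone, the silicon transporter gene Lsi1 with 1660 ± 121 and 1150 ± 281 (log2 fold change -0.55 ± 0.19, adjusted p = 0.2 over all genes, and -0.35 without RNAi replicate 1). Of 64 reporter probe sets, which match common transformation markers and other foreign sequences, 6 had groups that did not overlap, 3 higher and 3 lower in the RNAi arrays, where chance gives 6.4. The exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1, and the highest reporter signal on any array was 86.8.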

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

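SAM with no filter on low signal was chosen after seeing the data; the other settings were fixed before. The 601 calls became 37 on the signals as deposited (24 higher, 13 lower), 394 with no filter on low signal, 350 with the lower 70% of signal left out, 303 without a trend in eBayes, and 0 with Welch's test, which had 3001 at an unadjusted p under 0.05. SAM gave 551 calls, 450 of them shared with limma, and 105 with no filter, 103 of these higher. Leaving out 1 array gave 233 to 902 calls. With quantile normalization 547 of 603 calls were shared. With the lower 70% left out fewer probe sets were tested, which bounds the count; for the other settings the cause was not tested. With the replicate number as a block 424 probe sets passed, 388 of them shared. Same-numbered arrays did not deviate together (correlations of their deviations from the group means -0.045, 0.0084 and 0.0021), so the numbers were not taken as pairs.

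Of the 36 named genes past the threshold, 4 passed on the signals as deposited, 16 without a trend and 0 with Welch's test (limma and SAM passed 36 and 28), 27 with the replicate block, and 17 to 32 when 1 array was left out. The replicate block ended the calls of LEA19, CESA4, OsSPX2, NH3, OsSAPK2, CML5, CBL9, EXPB6 and IAA2. Without a trend the calls of RAB16B, RAB16C, PORA, LEA19, RAB21, CESA4, ABCG48, OPR10, AT5 and BC1L9 were lost. Also lost there were OsSPX2, Cht6, JAZ11, NH3, OsSAPK2, CML27, CBL9, EXPB6, IAA2 and IAA21. The 24 leading genes kept their direction in each setting that tested them. The 7 lists past the threshold became 0 with an estimated correlation and 0 with fry (2 and 3 lists at an unadjusted p under 0.05), and 3 to 8 when 1 array was left out, the fewest without RNAi replicate 1. In the other settings 6 or 7 lists passed. The lists for jasmonate and for the cell wall passed in 14 of 16 settings each, all but the estimated correlation and fry. Levels of OsSRT1 and OsSRT2 were not analysed here under any setting, and the reporter count of 6 has no alternative. Low signal limits fold changes: JAZ2 ran from 4.2 to 8.13 on the log2 scale over the settings.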

Other observations

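Further named genes past the threshold lay outside the rule for named genes and were picked after their values were seen. LOG, which activates cytokinins, had a signal of 12100 ± 1980 (SD, n = 3) in the controls and 7340 ± 64.8 in the RNAi arrays (log2 fold change -0.7 ± 0.12, limma adjusted p = 0.0246). The auxin efflux carrier gene OSPIN10a (also named OsPIN3a) fell by 0.81 ± 0.15 on the log2 scale (adjusted p = 0.0314), and BZR1, a transcription factor of brassinosteroid signalling, by 0.69 ± 0.12 (adjusted p = 0.0204). The OSPIN10a probe set has a name that marks it as reading several genes. The metal-nicotianamine transporter gene osysl16 fell by 0.84 ± 0.16 (adjusted p = 0.0341), beside the fall of the copper transporter gene COPT2. CBF3 (also named DREB1A), a cold and drought response factor, fell by 0.9 ± 0.15 (adjusted p = 0.0178). Among the rises, the glutamate dehydrogenase gene GDH went from 524 ± 46.7 to 1340 ± 113 (log2 fold change 1.33 ± 0.14, adjusted p = 0.00175) and the sucrose synthase gene OsSUS1 from 1250 ± 101 to 2170 ± 273 (log2 fold change 0.79 ± 0.14, adjusted p = 0.0233). DRB2, a double-stranded RNA binding protein, rose from 275 ± 33.8 to 833 ± 200 (log2 fold change 1.52 ± 0.21, adjusted p = 0.0078).

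Large changes also fell on probe sets with no gene listed. The strongest such rise was from 27.8 ± 5.25 to 1830 ± 218, and another probe set fell from 822 ± 163 to 67.4 ± 35.5 (log2 fold change 5.4 and -3.41, adjusted p = 6.43e-06 and 0.00117). Of the 601 called probe sets 207 had no single gene.

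The tests of wash run, RNA degradation and a wrong label were chosen after the results were seen. The others were written down before they were run. Those of the jasmonate list start from a pattern of the main comparison, so they were not chosen independently of it. The first pattern is that 181 probe sets passed with a change of at least 4-fold, 132 of them higher in the RNAi arrays. Probe sets whose names mark them as reading several genes, 44 with that of JAZ2 among them, made up 24.3% of these and 21.4% of all tested. Whether those 44 read other genes was not tested. Their share lay within the middle 95% of random sets, which reached 27.6%. This argues against cross-reading by probe sets with such names as the source of the set as a whole. Stretches of genome that differ between the plants may place such genes near each other, and 10 pairs of the set's genes lay 2 to 20 tested genes apart, where random sets had a median of 6 and a 95th percentile of 11, but 43.6% of the set had a position, so the test is void and this stays open (by direction, 4 pairs of falling genes against a 95th percentile of 3, and 3 of rising genes against 5). Directly adjacent pairs numbered 6 against a random 95th percentile of 1 and include the tandem genes RAB16C, RAB16B and RAB21 and the pair HSP17.4 and HSP18.1. Of the wash runs 0 held both groups. Wash run therefore cannot be told apart from the knockdown or any other difference between RNAi and untransformed plants.

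The second pattern is the lower level of the jasmonate list, which passed with camera's preset correlation and not with an estimated one. Without RNAi replicate 1 its median was -0.2 (95% bootstrap interval over genes -0.54 to -0.14), against -0.23 with all arrays, so that array alone is not its source. A bias against bright probe sets in the RNAi arrays could lower it. Its median lay at percentile 0.02 of 10000 random lists of the same size and signal. The middle 95% of these ran from -0.13 to 0.06 around a median of -0.04, so typical genes of that signal moved little. The jasmonate list was picked on these same fold changes, and random lists ignore correlation between members. The percentile is therefore no separate support for the shift. Wash run, the knockdown itself and any other difference between the RNAi and the untransformed plants stay open and cannot be told apart.

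The third pattern is RNAi replicate 1, which correlated with the other RNAi arrays at 0.9671 and 0.9676, while these correlated with each other at 0.9789. RNA degradation might set an array apart, but its 5' to 3' signal ratio was 0.139 for actin (0.0706 to 0.255 on the other 5 arrays) and 0.41 for Gapdh (0.408 to 0.68). A control array under an RNAi label might correlate best with the controls, and the mean correlation of RNAi replicate 1 with them was 0.955. All RNAi arrays shared a wash run, which could also bring them together, so this comparison cannot decide whether the label is wrong. No biological explanation was tested. The title of RNAi replicate 1 names transgenic line LM1 and the titles of the other RNAi arrays name LM2 and LM3, so a difference between lines stays open.

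The 6 arrays can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. The real split gave 601 calls and was the 1 of 10 with as many, with 0 the highest of the others. For the gene lists 2 of 10 splits, the real one included, put as many past the threshold: the real split gave 7 lists and the highest other also 7, with control replicates 1 and 3 and RNAi replicate 3 on one side.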
